A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

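The study hybridised RNA of a budding yeast ino80 mutant against RNA of wild-type yeast on 2-colour Agilent arrays. Per the labels, cells were grown in rich medium, held in G1 with the mating pheromone alpha-factor and let go into S phase with 0.02% methyl methanesulfonate (MMS), an agent that alkylates DNA. Total RNA was taken 45 minutes later. The labels number 3 ino80 extracts and 3 wild-type extracts, and each ino80 extract was hybridised against the wild-type extract of its number on 2 arrays with the dyes exchanged. The 6 arrays therefore hold 3 extract pairs, and both arrays of a pair were counted as 1 replicate (n = 3). The labels do not say whether the extracts came from separate cultures, so p-values measure the spread between these 3 pairs, which may be technical. The nature of the ino80 mutation and the other markers of the strains are not given in the sources used here.

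The arrays were read with Agilent Feature Extraction 9.5.3.1, per the file headers, which gives for each spot a mean intensity and a median local background intensity in Cy3 and in Cy5. The same deposited files hold the software's processed intensity, already background-subtracted and dye-normalized, and its log10 ratio of Cy5 over Cy3, per the file headers. A table of the authors' own comparison, made with limma per the submitters' processing notes, gives for each probe a deposited log2 ratio and a mean log2 intensity. It also gives a deposited score (the test statistic), a deposited p-value with its adjusted form, and a 0 or 1 call by the authors, another column with no unit. The background correction and normalization behind that table are not given in the sources used here. Its direction was found by taking INO80 as lower in ino80, so the sign of INO80 there is no separate check.

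Analysis started from the mean signals and local backgrounds, in R 4.3.3 with limma 3.58.1. Background was corrected with normexp and an offset of 50, and each array was normalized by loess with control spots at weight 0. Spots with the scanner software's outlier marks were left out (between 1.54% and 4.00% of spots per array); no spot was saturated. Each ratio was turned by the dyes in the labels to log2 of ino80 over wild type. The 7 spots of a probe were averaged, and each of the 6256 genes tested had 1 probe, so no rule for several probes of a gene was needed. Both arrays of a pair were averaged, so that a dye effect of a gene cancels, and the 3 pair means were fitted with lmFit and eBayes, with a two-sided test against 0 and Benjamini-Hochberg adjustment at 0.05. The dye effect of each gene was the mean of log2 Cy5 over Cy3 within each pair, in which the difference between the strains cancels, tested the same way. Values after ± are standard deviations of the 3 pair means.

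Gene names came from the array files. A table of RefSeq genes of assembly R64 was used only to update names and to find neighbours: 5756 systematic names matched, 500 did not and kept the file's name, and 1290 symbols were updated. The array files name no genome build, so no coordinates are given. Probe sequences were not checked against near-identical genes.

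Gene lists, the tests and the rule for naming genes were fixed before the data were examined. Named genes were INO80, the 15 largest rises and 15 largest falls among genes that passed, had the same sign on all 6 arrays and were well above background in at least 1 channel on all 6 arrays, and up to 4 members of each list with the smallest p. INO80 itself is among the 15 falls. Of the 29 lists, 27 were written out by name. The other two were taken from names: ribosomal proteins by their symbols, and subtelomeric open reading frames as the 10 outermost measured on each chromosome arm by systematic name. Lists were tested with limma's camera at a preset correlation between genes of 0.01, which compares a list with all other genes, with adjustment over the 29 lists. Camera with an estimated correlation and limma's fry, which asks whether a list's genes move on balance one way, were run as alternatives. Any other gene named was chosen after its values were seen.

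A signal was called well above background as the scanner software does, in at least 4 of the 7 spots of a probe. Median negative control signals in Cy3 were 1608 to 2229 against local backgrounds of 698 to 831, so Cy3 measures dim genes less well than Cy5. The number of arrays limits the precision, and the median standard deviation of a gene between pairs was 0.222 on the log2 scale. Bounds of the form "at least" were computed where a gene was not well above background in 1 strain, and none of these gave a usable bound.

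Whether equal numbers pair the arrays was checked from the data as well: deviations from the mean of their dye orientation correlated across genes between both arrays of a pair at 0.488, 0.139 and 0.176 for pairs 1, 2 and 3. Arrays of different pairs gave -0.472 to 0.276, the highest for pair 3 in Cy3 with pair 2 in Cy5. These deviations therefore set apart pair 1 alone. The correlation of ratios fitted within pairs was -0.05. It cannot test the pairing, since dye effects enter both arrays of a pair with opposite signs and lower it. The pairing itself comes from the labels, and it is built into the ratio on each array.

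The fit and the list test were tested on simulated data of 6256 genes in 20 draws, each with 200 changed genes and a list of 30 genes shifted by 0.5. Dye effects were the real ones, and the spread between pairs was that of the fit after eBayes had moderated it. Of genes changed by 0.5 on the log2 scale 33.8% were called with the right sign, against 98.5% at 1 and 100.0% at 2 and at 3. Among all calls 7.32% were false on average, above the 5% aimed at; the average over 20 draws replaced a single draw because the false share moved between draws. Of 560 lists without a shift 0 were called by camera, and the shifted list was called in all 20 draws. These lists were of independent genes, so they do not test correlated lists. The simulated noise was normal and equal on all arrays, no array had compressed ratios, and fewer genes changed than passed in the real data. The shares called and false may therefore differ in the real data.

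Alternatives covered the background correction, the scanner software's own ratios, median centring, between-array quantiles, a filter on dim probes, kept outlier spots, the variance model, each dye orientation alone, the 6 arrays with and without the pair as a block, separate-channel fits, the slide, leaving out each pair, and the authors' deposited table. Chosen after the data were seen were a background from negative controls, each slide alone, and leaving out 1 array with high signals on dim probes. On each slide alone, and in the pair of that array once it is left out, the dyes are not balanced, so dye effects do not cancel. The arrays lie on 2 slides, which also separate the scans, each with 1 array of every pair. The slide was tried as a random block and, after that result was seen, as a fixed block. Spike-in and control spots enter no test of genes.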

Results

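Expression of 6256 genes was compared between an ino80 mutant and wild-type budding yeast, both sampled 45 minutes after leaving a pheromone arrest into medium with 0.02% MMS. INO80 encodes the ATPase of a chromatin remodelling complex, and the comparison asks which RNAs differ in the mutant under this condition. Without untreated or earlier samples, no difference can be tied to MMS or to the time after release. A difference that the strains hold in any condition would look the same. The data are 6 arrays of 3 extract pairs, each pair hybridised with ino80 in Cy3 and again with ino80 in Cy5. Median spot signals were 6107 to 9495 in Cy3 and 7929 to 12070 in Cy5, and 5947 genes were well above background in at least 1 channel on every array. The array of pair 3 with ino80 in Cy3 stood apart, and it is named the bright array here. Its median negative control signal was 1090 in Cy5, against 85.4 to 93.7 on the other 5 arrays, and 2229 in Cy3, against 1608 to 1676, and 99.95% of its Cy5 spots were called well above background. The 456 genes with a mean Cy5 signal under 400 on the other arrays had a median Cy5 signal of 3584 there, against 164.7 to 272.1 elsewhere, and a median Cy3 signal of 3266, against 1657 to 1777.

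**Figure D1:**
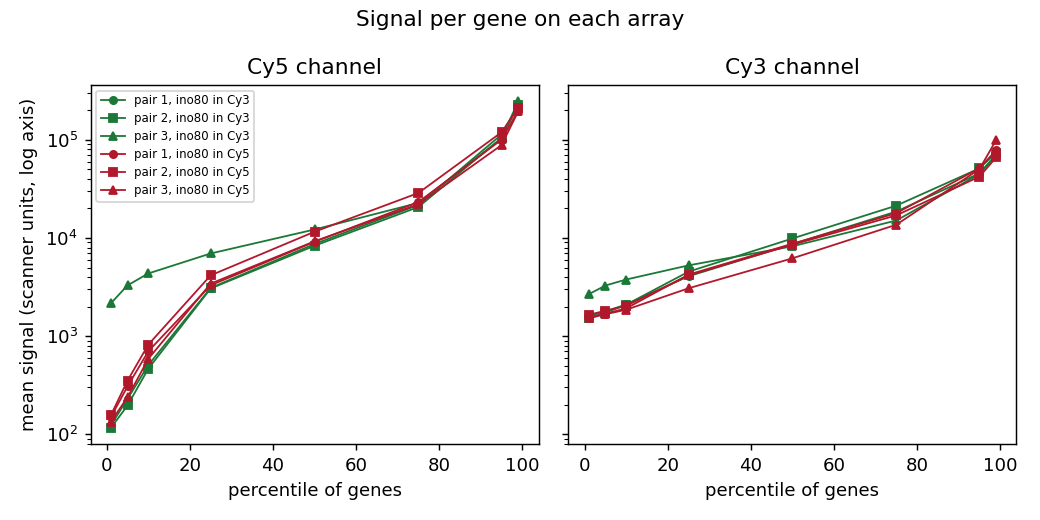
Mean spot signal per gene (scanner units, log axis) at percentiles of all genes, for the Cy5 and the Cy3 channel of each of the 6 arrays; colour gives the dye of ino80 and the symbol the extract pair. Genes with a mean Cy5 signal under 400 on the other 5 arrays have a median Cy5 signal of 3584 on the pair 3 array with ino80 in Cy3.

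INO80 (YGL150C) RNA was lower in the mutant on every array. The log2 ratio of ino80 over wild type was -5.29 ± 1.39 (SD, n = 3 pairs; limma, adjusted p = 0.00187). With ino80 in Cy3 it was -6.00, -7.19 and, on the bright array, -1.88 for pairs 1, 2 and 3, and with ino80 in Cy5 it was -5.49, -5.60 and -5.58. The ino80 channel was well above background on 4 of the 6 arrays. The size of this fall is therefore uncertain, while its direction was the same on all 6 arrays.

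In the mutant, 1008 genes rose and 1054 fell, together 2062 or 32.96% of those tested. Normalization centred the ratios of each array, and the median over all genes was 0.015. A shift of most genes to one side could therefore not be seen, and the near-equal numbers of rises and falls are not a finding. Changes of at least 2-fold were more often falls: 371 genes fell and 143 rose by that much, and 55 fell and 16 rose at least 4-fold. The 143 rises of at least 2-fold became 87 without background subtraction (against 269 falls), 215 with the scanner software's ratios (against 378) and 260 with ino80 in Cy5 alone (against 444). The largest fall after INO80 was that of HUG1, a DNA damage-induced inhibitor of ribonucleotide reductase, at a log2 ratio of -3.89 ± 0.15 (adjusted p = 0.000244). It was followed by genes of phosphate supply: SPL2 at -3.81 ± 0.31, the acid phosphatase genes PHO12 at -3.80 ± 0.06, PHO11 at -3.79 ± 0.05 and PHO5 at -2.82 ± 0.38, and the phosphate transporter gene PHO84 at -3.24 ± 0.35. PHO11 and PHO12 are near-identical, and their probes were not checked against each other. The other falls in this group were those of DIA1 (-3.23), HOR7 (-3.02), YOR385W (-2.92), MRH1 (-2.87), VPS73 (-2.82), the cell wall gene TIR3 (-2.71), the secreted glycoprotein gene YGP1 (-2.70) and the peroxisomal citrate synthase gene CIT2 (-2.64).

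The largest rise was that of TRP1 (YDR007W), an enzyme gene of tryptophan synthesis that is also a common selection marker, at 4.88 ± 1.92 (adjusted p = 0.00524). FIT1, a cell wall protein of iron uptake, rose by 4.16 ± 1.02, the glucose-repressed alcohol dehydrogenase gene ADH2 by 3.89 ± 0.79, the haem oxygenase gene HMX1 by 3.58 ± 0.52 and the stress gene HSP12 by 3.27 ± 0.20. Rises between 2.04 and 2.68 were seen for CYC1 (cytochrome c), NCE103 (carbonic anhydrase), TSA2 (a peroxidase), SRL1, OSI1, MF(ALPHA)2 (alpha-factor precursor), YOR248W, PDC6, SNZ3 and GRE1. YOR248W is adjacent to SRL1 by its systematic name. In the wild-type channel TRP1, HMX1 and MF(ALPHA)2 were well above background on 3 of the 6 arrays, so the size of these rises is uncertain. On the bright array the ratio of TRP1 was 1.05 and that of MF(ALPHA)2 was 0.18, against 4.28 to 6.10 and 2.03 to 3.05 on the other 5 arrays.

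**Figure D2:**
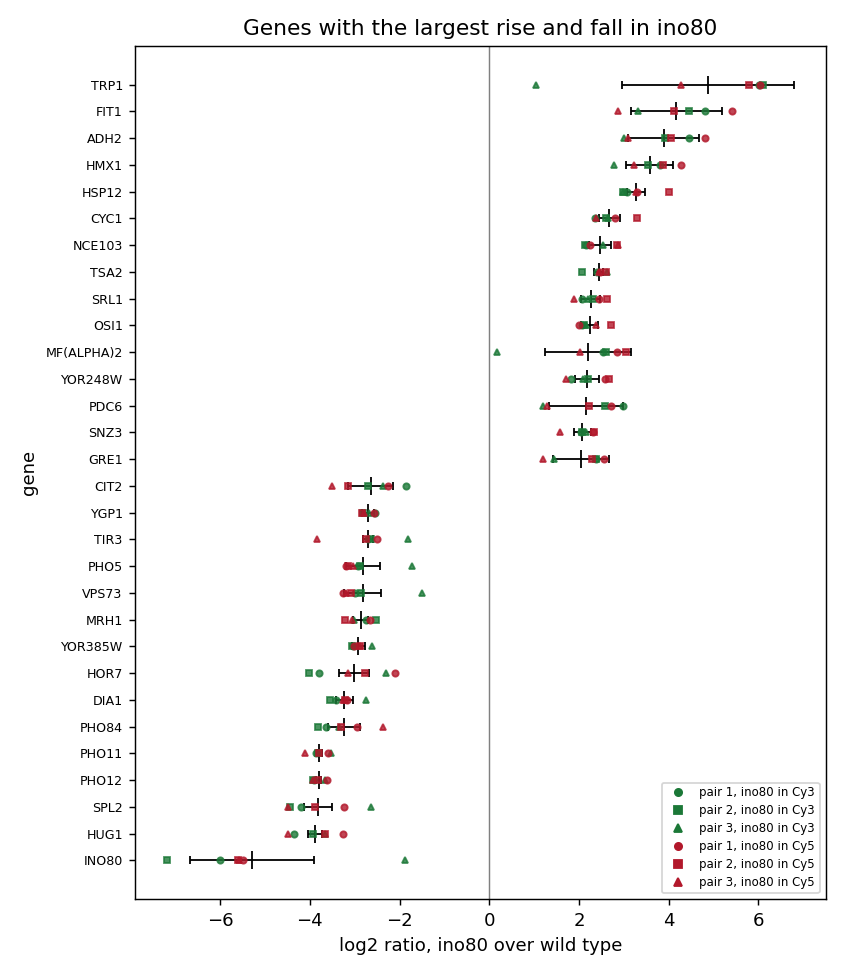
Log2 ratio of ino80 over wild type for the 15 genes with the largest rise and the 15 with the largest fall; green and red points are arrays with ino80 in Cy3 and in Cy5, symbols are the extract pairs, and black marks show the mean ± SD of the 3 pair means. Each gene has the same sign on the 6 arrays, and on the pair 3 array with ino80 in Cy3 INO80 is at -1.88 and TRP1 at 1.05.

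Of the 2062 genes that passed, 1769 had the same sign on all 6 arrays, and 2856 genes had an unadjusted p under 0.05. The number that passed was 1045 without the bright array and 606 without pair 2. In pairs 1 and 2 alone, without either array of pair 3, 2693 genes with a ratio on every array passed. The drop to 1045 is therefore not due to the loss of the bright array alone. Without it pair 3 holds 1 dye orientation, and its dye effects do not cancel. Of the named genes besides INO80, 24 calls ended without the bright array and 4 without pair 3. On each slide alone, with 1 array of every pair, it was 680 and 666. With the slide as a fixed block 2082 genes passed. With the slide as a random block 3830 did, at a fitted correlation within slides of -0.289. A negative correlation makes the standard errors smaller, so 3830 is not taken as a count of changed genes.

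Genes of phosphate supply fell as a group: of 21, 15 fell and 1 rose (16 and 1 adjusted over the list alone), with a median log2 ratio of -1.71. Besides those above, the polyphosphate polymerase genes VTC1, VTC3 and VTC4, the transporter gene PHO89 and the regulator gene PHO81 fell, and the transporter gene GIT1 rose by 0.89, an uncertain size since its wild-type channel was well above background on 3 arrays. The list lay below other genes (camera, adjusted p = 1.15e-06; adjusted p = 0.568 with an estimated correlation), with its median below 0 on all 6 arrays. In it 14 genes fell without the bright array, and 13 fell and 0 rose without pair 2. Phospholipid genes of the inositol response went both ways: of 21, 3 rose and 4 fell (3 and 4 adjusted over the list alone), and the list did not pass (adjusted p = 0.686). The phosphatidylserine synthase gene CHO1 rose by 1.27 ± 0.06, and the phospholipid methyltransferase gene OPI3 (-1.29 ± 0.02), the fatty acid synthase gene FAS1 (-1.17 ± 0.21) and CPT1 (-0.62 ± 0.12) fell. Without the bright array 1 of these genes rose and 4 fell; without pair 2 1 rose and 2 fell, and CPT1 did not pass (adjusted p = 0.2); without pair 3 3 rose and 8 fell.

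DNA damage-induced genes changed in both directions: of 28, 11 fell and 5 rose (12 and 5 adjusted over the list alone), with a median of -0.29, and the list did not pass (adjusted p = 0.0692). Besides HUG1, the stress gene DDR48 (-1.99 ± 0.28) and the ribonucleotide reductase gene RNR2 (-1.81 ± 0.23) fell, while the peroxidase gene TSA2 rose by 2.44 ± 0.10. The ribonucleotide reductase genes RNR3 (-1.10) and RNR4 (-1.69) also fell, and the large subunit gene RNR1 was at 0.41 (adjusted p = 0.084). These 3 genes were chosen after their values were seen. Without the bright array 9 members fell and 5 rose, and without pair 2 7 fell, 2 rose and the list passed (adjusted p = 0.0462), as it did with fry (0.0153).

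None of the 4 lists of repair and checkpoint genes passed. In DNA damage tolerance 2 of 20 genes rose and 2 fell (0 and 1 adjusted over the list alone; adjusted p = 0.827): the ubiquitin-conjugating partners MMS2 (-1.34 ± 0.40) and UBC13 (-0.72 ± 0.48) fell, and CTF18 and POL32 rose by 0.42 and 0.38. In homologous recombination 2 of 28 rose and 2 fell (0 and 0 adjusted over the list alone; adjusted p = 0.837), namely RTT107 (0.50), EXO1 (0.43), YEN1 (-0.44) and CSM2 (-0.43). Of 22 base and nucleotide excision repair genes 7 fell and 2 rose (7 and 2 adjusted over the list alone; adjusted p = 0.827), with APN1 (-0.66), MAG1 (-0.64), RAD16 (-0.56) and RAD1 (-0.55) among the falls. Of 22 S-phase checkpoint genes 3 rose and 2 fell (3 and 2 adjusted over the list alone; adjusted p = 0.895). The phosphatase genes PTC3 and PPH3 rose by 1.44 ± 0.42 and 0.74 ± 0.24 and RAD24 by 0.56 ± 0.16, while the kinase gene DUN1 fell (-0.65 ± 0.04). Of the genes named here, only MMS2 and PTC3 passed without pair 2; the others had adjusted p of 0.104 to 0.42. Leaving out the bright array ended the calls of UBC13, CTF18, POL32, RTT107, YEN1, EXO1, CSM2, APN1, RAD1, RAD16 and RAD24 (adjusted p = 0.0636 to 0.199). Without pair 3 CTF18, POL32, EXO1 and CSM2 did not pass (0.0559 to 0.0869), nor did POL32 and EXO1 without pair 1 (0.0727 and 0.0661). In excision repair 1 gene rose and 1 fell without the bright array, and 0 and 0 without pair 2. In tolerance 0 rose and 1 fell in both of these cases, and 0 rose and 4 fell without pair 3. In homologous recombination 0 rose and 0 fell in both cases, 3 rose and 6 fell without pair 1, and 1 rose and 2 fell without pair 3. In the checkpoint list 2 rose and 1 fell without the bright array, 1 and 0 without pair 2, 4 and 4 without pair 1, and 3 and 5 without pair 3.

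Cell cycle lists moved in opposite directions. Of 11 histone genes 7 rose and 0 fell (9 and 0 adjusted over the list alone), with HTB2 at 1.80 ± 0.47, HTA2 at 1.54 ± 0.66, HHT1 at 0.90 ± 0.24 and the linker histone gene HHO1 at 0.71. Of 34 G1/S genes 17 rose and 3 fell (18 and 4 adjusted over the list alone): the cohesin genes PDS5 and SMC3 rose by 1.17 and 1.00, and the cyclin gene CLN1 (-0.84 ± 0.04) and the fatty acid elongase gene ELO1 (-1.82 ± 0.11) fell. Of 23 G2/M genes 11 fell and 0 rose (12 and 0 adjusted over the list alone), including the mitotic cyclin gene CLB1 (-1.45 ± 0.09), the cytokinesis genes CHS2 (-1.12) and HOF1 (-1.44), and YNL058C (-2.32). The medians were 0.79, 0.43 and -0.61, each with the same sign on all 6 arrays (camera, adjusted p = 0.000453, 0.00627 and 0.000146; adjusted p = 0.607, 0.568 and 0.568 with an estimated correlation), and with fry the histone list did not pass (adjusted p = 0.11). Of 24 M/G1 genes 11 fell and 3 rose (12 and 3 adjusted over the list alone), with a median of -0.37 and no call for the list (adjusted p = 0.102). The cell wall gene PST1 (-1.72) and the replicative helicase gene MCM3 (-0.81) fell, and the daughter-cell genes CTS1 and DSE1 rose by 1.01 and 0.79. On leaving out the bright array 4 histone and 7 G1/S genes rose, 9 G2/M genes fell, 2 M/G1 genes rose and 7 fell, HHT1 did not pass (adjusted p = 0.0552) and the M/G1 list passed (adjusted p = 0.05). It also passed on slide 1 alone (0.046) and with ino80 in Cy5 alone (0.0164), but not on slide 2 alone (0.172) or with ino80 in Cy3 alone (0.463). On leaving out pair 2, 2 histone, 4 G1/S and 1 M/G1 genes rose, 1 G1/S, 8 G2/M and 3 M/G1 genes fell, and HHT1, HHO1, CLN1, MCM3 and DSE1 did not pass (adjusted p = 0.0646 to 0.0895). Without pair 1 all 11 histone genes rose.

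Pheromone response genes were lower. Of 25, 9 fell and 1 rose (10 and 2 adjusted over the list alone), with a median of -0.31, below 0 on all 6 arrays (camera, adjusted p = 0.0115; adjusted p = 0.568 with an estimated correlation). PRM8 (-2.10 ± 0.07), PRM4 (-1.505), the G protein gene GPA1 (-1.60 ± 0.27) and the cell cycle inhibitor gene FAR1 (-1.05 ± 0.14) fell, and KAR3, a motor protein gene of nuclear fusion, rose by 0.81. In this list 7 genes fell without the bright array, 6 fell and 0 rose without pair 2, and 10 fell and 2 rose without pair 1. Mating-type-specific genes split: 5 of 14 rose and 6 fell (5 and 7 adjusted over the list alone; adjusted p = 0.694). The alpha-factor receptor gene STE2 (-1.90 ± 0.35), the alpha-factor protease gene BAR1 (-1.27 ± 0.19) and RME1 (-1.43 ± 0.07) fell, whereas the a-factor precursor gene MFA1 rose by 1.84 ± 0.47. The alpha-factor precursor gene MF(ALPHA)2 and SAG1, normally specific to alpha cells, rose by 2.20 and 0.93, and MF(ALPHA)1 rose too. Of 31 meiosis and sporulation genes 5 rose and 4 fell (5 and 4 adjusted over the list alone; adjusted p = 0.463): SPS1 rose by 1.53 ± 0.42, and MEI4 (-1.08), SMK1 (-0.66) and SPS19 (-0.55) fell. The sizes for SPS1, SMK1 and MEI4 are uncertain: the wild-type channel of SPS1 and SMK1 was well above background on 3 of the 6 arrays, the ino80 channel of SMK1 and MEI4 on 4, and on the bright array SPS1 was at 0.33 and SMK1 at -0.11. With ino80 in Cy5 alone the list passed (adjusted p = 0.0164). Leaving out the bright array left 2 rises and 1 fall among these, without MEI4 and SPS19 (adjusted p = 0.0531 and 0.0628). Leaving out pair 2 left 1 and 1, without SMK1 and SPS19 (0.233 and 0.194); leaving out pairs 1 and 3 gave 9 and 3, and 6 and 9.

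Ribosome biogenesis genes rose together: 34 of 65 rose and 0 fell (36 and 0 adjusted over the list alone), with a median of 0.475, above 0 on all 6 arrays (camera, adjusted p = 6.28e-09; adjusted p = 0.568 with an estimated correlation). RRN3, a factor of RNA polymerase I, rose by 0.79 ± 0.02, and the processing factor genes NOP7, RRP9 and DBP9 by 0.79 ± 0.07, 0.76 ± 0.13 and 0.75. The number of members that rose was 8 without the bright array, 2 without pair 2, and 0 and 5 on slides 1 and 2, while the list passed in each of these; without pair 1 40 rose and 1 fell. Without pair 2 the 4 genes named had adjusted p of 0.0687 to 0.0904.

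Of 138 ribosomal protein genes 11 fell and 3 rose (0 and 0 adjusted over the list alone), and their direction differed between the dye orientations. The list median was -0.31 (camera, adjusted p = 0.000306; adjusted p = 0.885 with an estimated correlation), and with fry the list did not pass (adjusted p = 0.459). The median was -1.65, -0.96 and -0.15 on the arrays of pairs 1, 2 and 3 with ino80 in Cy3, and -0.06, 0.64 and 0.27 with ino80 in Cy5. With the Cy5 orientation alone the list lay above other genes, at a median of 0.31 (adjusted p = 0.000242). Without pair 1 the list did not pass (adjusted p = 0.627), with 11 falls and 6 rises. There was 1 fall and 0 rises without pair 2, 84 falls and 3 rises without pair 3, and 3 falls and 1 rise without the bright array. RPL7B (-1.33 ± 0.47), RPL8A (-0.78 ± 0.24) and RPS14A (-0.69 ± 0.24) fell and RPS14B rose by 0.70 ± 0.24, but RPS14A was at 0.03 with the Cy5 orientation alone. Without the bright array RPL7B, RPS14A and RPS14B did not pass (adjusted p = 0.0625 to 0.0818), and without pair 2 RPL8A, RPS14A and RPS14B did not (0.0836 to 0.163).

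Iron regulon genes were mostly higher. Of 27 measured, 14 rose and 3 fell (16 and 3 adjusted over the list alone), with a median of 0.625, above 0 on all 6 arrays (camera, adjusted p = 0.000507; adjusted p = 0.607 with an estimated correlation). Besides FIT1 and HMX1, the iron permease gene FTR1 rose by 1.51 ± 0.15, and the reductase gene FRE3 fell (-1.41 ± 0.12). Here 13 rose and 2 fell without the bright array, and 9 rose and 1 fell without pair 2. Of 27 methionine and sulfur genes 10 rose and 3 fell (11 and 3 adjusted over the list alone; adjusted p = 0.116): MHT1 rose by 1.38 ± 0.03, the sulfate permease gene SUL2 by 1.33 ± 0.23 and MET10 by 1.15 ± 0.06, and the transporter gene MUP3 fell (-1.235). That list passed without pair 2, with 5 rises and 1 fall, and without pair 3, with 13 and 5 (adjusted p = 0.0374 and 0.0471); without the bright array 5 rose and 3 fell.

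Of 27 sterol synthesis genes 9 fell and 1 rose (10 and 3 adjusted over the list alone), with a median of -0.29, below 0 on all 6 arrays (camera, adjusted p = 0.0353; adjusted p = 0.568 with an estimated correlation). The squalene epoxidase gene ERG1 (-2.20 ± 0.18) fell most among those named, followed by ERG25 (-1.32 ± 0.06), ERG9 (-1.14 ± 0.18) and ERG7 (-0.90 ± 0.03). The list did not pass without pair 1 or pair 3 (adjusted p = 0.0604 and 0.0606) or with ino80 in Cy3 alone (0.255), and 5 members fell without the bright array as without pair 2, where 0 rose; 12 fell and 2 rose without pair 3. Of 45 amino acid synthesis genes 15 fell and 7 rose (17 and 7 adjusted over the list alone; adjusted p = 0.0524). The lysine genes LYS9 (-2.15 ± 0.43) and LYS1 (-1.89 ± 0.05), the glutamine synthetase gene GLN1 (-1.94 ± 0.18) and HIS4 (-1.48 ± 0.27) fell. The list passed without background subtraction (0.0294), with median centring (0.0162), with ino80 in Cy5 alone (0.0164), on slide 2 alone (0.0289) and with fry (0.0295). In it 7 fell and 3 rose without the bright array, and 6 and 3 without pair 2.

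Genes of hexose transport and glucose repression changed in both directions: of 41, 9 fell and 5 rose (9 and 5 adjusted over the list alone; adjusted p = 0.694), with falls of the hexose transporter genes HXT1 (-2.58 ± 0.21), HXT3 (-2.10 ± 0.21) and HXT7 (-1.26 ± 0.17) and the rise of ADH2. Of 44 respiration genes 10 fell and 5 rose (10 and 5 adjusted over the list alone; adjusted p = 0.557), with falls of COX5B (-1.36 ± 0.11), RIP1 (-0.95) and SDH2 (-0.83) and the rise of CYC1. The numbers without pair 2 were 5 and 2 hexose genes and 2 and 3 respiration genes, and SDH2 did not pass (adjusted p = 0.0784). Of the respiration genes 7 fell and 2 rose without the bright array, 12 and 8 without pair 1, and 15 and 7 without pair 3.

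Stress genes also went both ways: of 36 genes of the environmental stress response 16 fell and 9 rose (18 and 9 adjusted over the list alone; adjusted p = 0.0893, and 0.05 with fry, which passed), with falls of YGP1, the hexokinase gene HXK1 (-2.01 ± 0.12) and the chaperone gene HSP42 (-1.52 ± 0.18) and the rise of HSP12. Of 20 heat shock chaperone genes 5 fell and 4 rose (9 and 5 adjusted over the list alone, camera adjusted p = 0.694). CPR6 fell (-1.32 ± 0.18), and the endoplasmic reticulum chaperone gene KAR2 and the mitochondrial one SSC1 rose by 1.21 ± 0.14 and 0.67 ± 0.05. Of 34 proteasome genes 3 rose and 0 fell (2 and 0 adjusted over the list alone; adjusted p = 0.694): RPN2, the regulator gene RPN4 and RPT2 rose by 0.71, 0.66 and 0.48, and RPN5 was at 0.60 (adjusted p = 0.0554). Without pair 2 SSC1, RPN2, RPN4 and RPT2 did not pass (adjusted p = 0.0741 to 0.257), 2 chaperone genes rose and 2 fell, and 0 proteasome genes rose. Omitting the bright array gave 5 rises and 12 falls in the stress list, 2 and 2 among chaperones, and no call for RPT2 (adjusted p = 0.0657). Omitting pair 1 gave 6 rises and 1 fall in the proteasome list, RPN5 among them (adjusted p = 0.00264), and 7 rises and 7 falls among chaperones; omitting pair 3 gave 4 rises and 1 fall in the proteasome list.

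Of 15 genes of the INO80 complex, INO80 included, 3 rose and 2 fell (5 and 3 adjusted over the list alone; adjusted p = 0.694). ARP4, also a subunit of other complexes, fell (-0.89 ± 0.32), and IES1 and IES2 rose by 0.81 ± 0.13 and 0.55 ± 0.22. Of 21 other chromatin remodelling and H2A.Z exchange genes 4 rose and 0 fell (4 and 0 adjusted over the list alone; adjusted p = 0.0864): RSC8 by 0.87 ± 0.20, SNF12 by 0.70 ± 0.11, the H2A.Z gene HTZ1 by 0.67 ± 0.16 and STH1 by 0.56 ± 0.23. ARP4, IES2, HTZ1 and STH1 did not pass without the bright array (adjusted p = 0.0512 to 0.101), nor, like SNF12, without pair 2 (0.0642 to 0.336). The numbers that rose and fell were then 1 and 1 in the complex in both cases, and 2 and 1 other chromatin genes rose, against 7 without pair 1 and 6 without pair 3. The chromatin list passed without the bright array (adjusted p = 0.05), on slide 1 alone (0.046) and with fry (0.028).

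Of 320 subtelomeric reading frames 55 fell and 48 rose (54 and 48 adjusted over the list alone; adjusted p = 0.619), and PHO12, PHO11, YDL241W (-2.36 ± 0.09) and GTT1 (-2.10 ± 0.12) were the members named. There 33 fell and 35 rose without the bright array, and 21 and 15 without pair 2. Of 10 laboratory marker genes 1 rose and 3 fell (1 and 3 adjusted over the list alone; adjusted p = 0.36): TRP1 rose, and ADE2 (-1.295), ADE1 (-0.46 ± 0.13) and URA3 (-0.62 ± 0.39) fell. URA3 was well above background on the bright array and on no other, so its fall is uncertain. URA3 and ADE1 did not pass without that array (adjusted p = 0.0863 and 0.0727) or without pair 2 (0.348 and 0.374), which left 1 fall in the list in both cases, against 6 falls and 2 rises without pair 3.

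In all, 9 of the 29 lists passed camera, 0 passed with an estimated correlation and 11 passed fry. The loss with an estimated correlation does not show that correlated genes account for every call. For G1/S genes the estimate was -0.002, below the preset 0.01, yet the camera p went from 0.00151 to 0.0673. In lists with higher estimates, up to 0.666 for ribosomal proteins, correlation may contribute. The 9 lists also passed with the slide as a fixed block, on each slide alone and without the bright array, although the dyes are not balanced on a slide. In other settings some did not. The ribosomal protein list did not pass without pair 1 and reversed with ino80 in Cy5 alone. The sterol list did not pass without pair 1, without pair 3 or with ino80 in Cy3 alone. The median, mean and test of a list differed in sign for the INO80 complex, DNA damage tolerance, excision repair, S-phase checkpoint and laboratory marker lists, none of which passed.

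**Figure D3:**
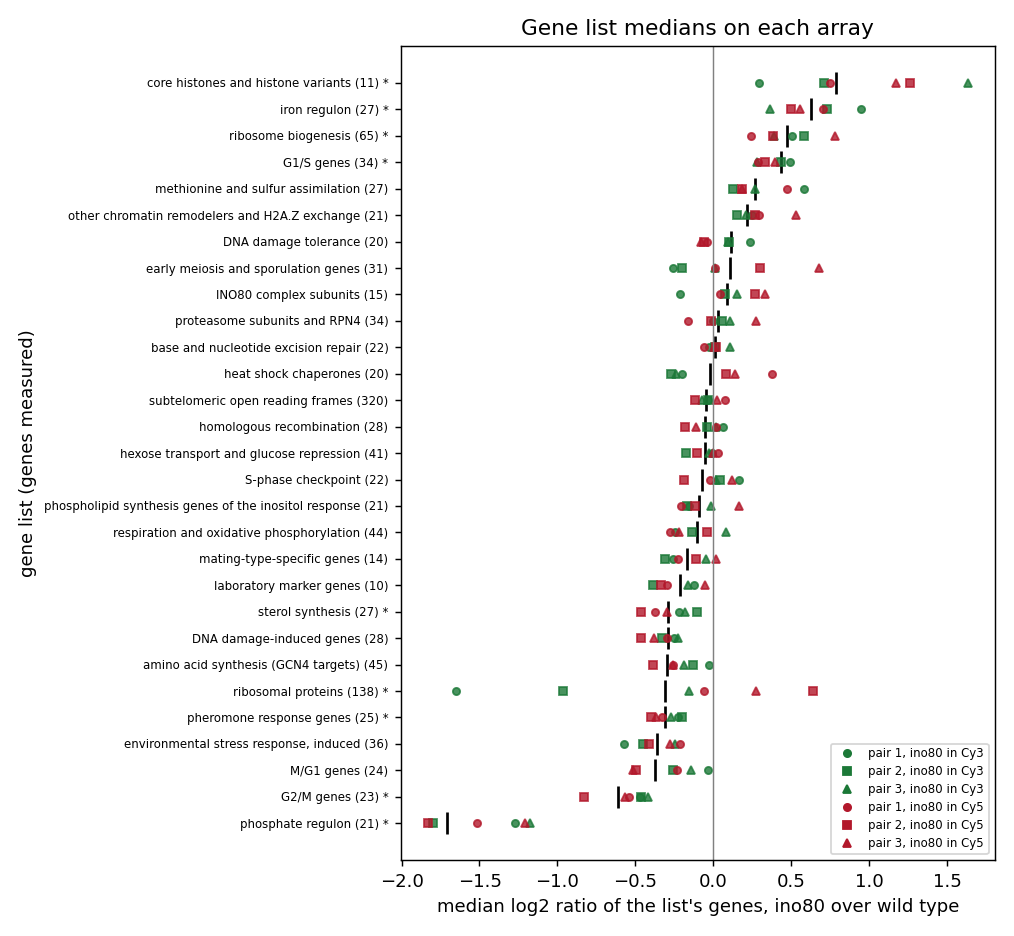
Median log2 ratio of ino80 over wild type of each of the 29 gene lists (genes measured in brackets) on each array, green with ino80 in Cy3 and red with ino80 in Cy5, with the extract pair as symbol, the median of the fitted ratios as a black tick and a star at lists past the camera threshold. Ribosomal protein medians run from -1.65 to -0.15 with ino80 in Cy3 and from -0.06 to 0.64 with ino80 in Cy5.

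The authors' deposited table marked 1211 genes as different, 489 higher and 722 lower in ino80, all with a log2 ratio of at least 0.585 in size. Of these, 1187 also passed here, and all 1211 had the same sign. At an adjusted p under 0.05 that table held 1202 higher and 1203 lower genes, and its log2 ratios correlated across genes with those here at r = 0.994; genes are not independent replicates, and both rest on the same arrays. INO80, from which the direction of the authors' deposited table was found, stood at -4.05 there.

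The exchange of dyes also gave each gene's dye effect, in which the strains cancel. For 42 genes log2 Cy5 over Cy3 differed from 0 (limma), with 28 brighter in Cy5 and 14 brighter in Cy3, and 28 by at least 2-fold; 1339 genes had an unadjusted p under 0.05. The ribosomal protein gene RPL39 (2.11) and the mitochondrial intron gene AI3 (-1.89), chosen after their values were seen, were the extremes, and AI3 was well above background on 0 arrays. Of the 42 genes 12 were also called between the strains. Leaving out pairs 1, 2 and 3 gave 360, 140 and 1599 genes with a dye effect. Across genes, the ratios of both arrays of a pair correlated at 0.692, 0.685 and 0.48 for pairs 1, 2 and 3. Arrays of different pairs correlated at 0.494 to 0.906 with the same dyes and at 0.39 to 0.705 with opposite dyes.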

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

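Tests chosen only after the result was seen were those of the swapped pair 3 array, on either reference, and of the pheromone, dye and M/G1 genes for the cell cycle lists; the tests of TRP1, of the slopes by signal and of the sign assignments were written before. Differences between the dye orientations are given first. Ribosomal protein genes had a mean of array medians of -0.922 with ino80 in Cy3 and 0.284 with ino80 in Cy5, and a camera test of the dye effect gave an adjusted p of 5.1e-31. Meiosis and sporulation genes were at -0.148 and 0.33 (adjusted p = 4.02e-05), and M/G1 genes at -0.147 and -0.414 (adjusted p = 0.0237). The orientations therefore differ in size for M/G1 genes and in sign for the ribosomal protein and meiosis lists. These dye tests used the preset correlation between genes alone. In the strain comparison the estimates were higher, at 0.666, 0.156 and 0.261 for the ribosomal protein, meiosis and M/G1 lists. Correlated genes may therefore make these dye p-values too small, and the size of 5.1e-31 is not relied on. Single genes with a dye effect numbered 42 of 6256 (limma), but 1339 had an unadjusted p under 0.05. More passed on leaving out any of the pairs, so 42 does not show that dye effects are rare. In data that no comparison used, the spike-in probe with the lowest Cy5 signal of the 10 on the bright array read 5243 there, against 326.9 to 529.7 on the other 5 arrays and 1090 for the negative controls of that array. The lowest spike-in probe was raised there in Cy3 too, at 4645 against 1715 to 2002.

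The first pattern weighed is the rise of TRP1. The other tryptophan synthesis genes TRP2, TRP3, TRP4 and TRP5 had a median of 0.003 (SD of the pair medians 0.019), which argues against a shared rise of the tryptophan synthesis genes. A TRP1 gene present in the ino80 strain and missing from the wild-type strain may explain it, and wild-type TRP1 was well above background on 3 of 6 arrays, a count that met the bound written against this explanation. That bound is set aside, a reading chosen after the values were seen, because 1 of the 3 is the bright array, where the markers URA3, LEU2 and HIS3 were also well above background although they were so on no other array. Without it the count is 2 of 5, with 0 of the 3 arrays that have wild type in Cy3. On these 2 arrays wild-type TRP1 read 226.4 and 314.1 in Cy5. There URA3, LEU2 and HIS3 read 94.28 to 120.6 and were not well above background. However, INO80 in the ino80 channel read 238, 251.6 and 214.7 in Cy5, each also well above background. A reading of this size is therefore no clear sign of a TRP1 transcript in the wild type. Presence and absence of the gene cannot be told apart here, since the origin of this low signal was not tested, and a change in transcription stays open.

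The second pattern is the smaller ratios on the bright array, whose slope on the mean of the other 5 arrays was 0.624 against 0.936 to 1.071 for the rest, over 2693 genes called in pairs 1 and 2, a choice that can lower the slopes of pair 3. Dim genes were raised there in both channels. Their medians were 3584 in Cy5 and 3266 in Cy3, against 164.7 to 272.1 and 1657 to 1777 elsewhere. Such extra signal, larger in Cy5, may compress their ratios. With the 2693 genes in 3 equal groups by signal, the slope was 0.838 in the brightest group and 0.374 in the dimmest. The difference was 0.464 (SE 0.024). Median local backgrounds were not raised there, at 85.5 in Cy5 and 776 in Cy3, against 80 to 84 and 698 to 831 elsewhere. Nor was the extra signal even over spots. In Cy5 HIS3 read 3137 and URA3 8158 there, with negative controls at 1090. A smaller effect in extract pair 3 itself stays open for the genes as a whole: its swapped array had a slope of 0.936 (SE 0.016), but on a mean that holds the bright array, and on the arrays of pairs 1 and 2 alone it had 0.862 (SE 0.015). On that shared reference the swapped array exceeded the bright one by 0.432 (SE 0.027) in the dimmest group, which argues against a smaller effect as the whole cause there, and by -0.001 (SE 0.029) in the brightest group, at slopes of 0.823 and 0.824, where a smaller effect in pair 3 may account for the pattern. The source of the extra signal was not tested, and no biological explanation was tested.

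The third pattern is higher histone and G1/S genes with lower G2/M genes. Cells still held by the pheromone would keep its response genes high, but their median was -0.31 (SD of the pair medians 0.039). This argues against such a hold only if ino80 cells respond to the pheromone as wild type does. That was not tested, and the receptor gene STE2 (-1.90) and the G protein gene GPA1 (-1.60) were lower. A dye bias is argued against because the histone minus G2/M difference of medians was 0.759 to 2.095 over the 6 arrays. An earlier position of ino80 cells in the cell cycle may explain it, but the M/G1 median of -0.373 does not decide: the list did not pass (adjusted p = 0.102; 0.0164 to 0.885 over the alternatives), its size differed between dyes, and it passed without the bright array (0.05), on slide 1 alone (0.046) and with ino80 in Cy5 alone (0.0164). DNA content was not analysed here, and a direct effect of ino80 on these genes stays open and untested.

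For the number of genes past the threshold, the 4 assignments of signs to the 3 pairs are too few for a share under 0.05: 1 of them, the real one, gave 2062 genes, and the highest of the others gave 0.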

How the results depend on the processing

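Each slide alone, leaving out the bright array, the background from negative controls, and the fixed slide block after the random one had been seen were chosen after seeing the data. The number of genes higher and lower together, 2062, was 1045 (430 higher, 615 lower) without the bright array, 680 (231 and 449) on slide 1 and 666 (246 and 420) on slide 2, each with fewer arrays. In these settings the dyes are also not balanced, so dye effects do not cancel. With the slide as a random block the number was 3830 (1962 and 1868) at a fitted correlation of -0.289, against 2082 with the slide as a fixed block. That negative correlation makes the standard errors smaller, so 3830 is not taken as a count of changed genes. With the extract pair as replicate block 2530 genes passed, and 2428 with no block. The correlation fitted within pairs was also negative, at -0.05, and with no block both arrays of a pair count as separate replicates. Neither number is taken as a count of changed genes. Leaving out each pair gave 606 to 2694 genes, 185 to 1263 higher and 421 to 1431 lower. Genes higher numbered 653 with median centring, 1521 with separate channels and no replicate block, and 615 with ino80 in Cy5 alone. Genes at least 2-fold higher numbered 87 without background subtraction, 215 with the scanner software's ratios and 260 with ino80 in Cy5 alone. Lists past camera fell to 0 with an estimated correlation. Genes with a dye effect numbered 351 with median centring, 9 without background subtraction and 140 to 1599 on leaving out each pair. With ino80 in Cy5 alone the log2 ratio of RPS14A was 0.0307 (adjusted p = 0.9149) and the ribosomal proteins list at 0.3084, both reversed. Where fewer arrays do not account for a change, the cause was not tested. Of 128 named genes besides INO80, RPN5 without a call among them, 124 stayed on the same side of the threshold in the same direction without background subtraction, 116 with median centring, 104 without the bright array, 88 on each slide alone, 87 without pair 2 and 124 without pair 3. Between-array quantiles change no ratio and so test nothing, and the choice among probes of a gene was not run, since each gene has 1 probe. Signal over background limits Cy3 most, where negative controls read 1608 to 2229.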

Other observations

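Process terms, tested only after the results were seen, gave the following; the test of neighbouring genes by Pearson's r was written before its result was seen, and that by rank was chosen after. Genes annotated to processing of 20S pre-rRNA were higher in ino80: 11 of 19 rose and 0 fell, with a median of 0.44 (camera, adjusted p = 0.00246). Terms for rRNA modification (8 of 14 rose, median 0.54, adjusted p = 0.00271), 35S primary transcript processing (9 of 25, 0.31, 0.0175) and large ribosomal subunit assembly (5 of 13, 0.39, 0.0452) were also higher. Microtubule nucleation genes were higher as well, with 7 of 22 rising and a median of 0.34 (adjusted p = 0.0229), while gluconeogenesis genes were lower, with 11 of 21 falling, 3 rising and a median of -0.44 (adjusted p = 0.0175). These 6 were the terms past the threshold of 77 with at least 10 genes, and 0 passed with an estimated correlation (adjusted p = 0.953). The rRNA terms hold genes of the ribosome biogenesis list and are not separate evidence.

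If the ino80 mutation acted on promoter regions, divergent neighbours that share one might change together. Log2 ratios correlated across 1464 divergent neighbour pairs at r = 0.079 (Spearman's rho 0.127), across 2734 tandem pairs at 0.071 (rho 0.042) and across 1445 convergent pairs at 0.001 (rho -0.003). The difference between divergent and convergent pairs was 0.078 (permutation p = 0.0292 over 10000 permutations), below the 0.1 set beforehand for a shared effect. By rank it was 0.131 (permutation p = 5e-04), above that size. The measures therefore differ on whether the bound was met, and a weak shared effect on divergent neighbours stays a hypothesis. Genes are not independent replicates, and strands were taken from systematic names.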
